A study of Mus musculus with 9 samples.

How the data were processed

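RNA from Caki cells stably carrying an empty retroviral vector (MX), wild-type YAP1 or YAP1-S127A was sequenced, with 3 libraries per group and 9 in all. Per the labels, cells were selected with G418, and stranded libraries of messenger RNA were sequenced on an Illumina HiSeq instrument. The deposited values are raw read counts per gene, 1 column per library, whole numbers with no normalization visible. Per the submitters' processing notes HISAT2, Cufflinks and Salmon 1.9.0 were used with the mouse build GRCm39, with no role or order given. The gene identifiers of the deposited count table are human Ensembl genes, so the named mouse build does not describe it. The human build, the annotation release, the counting program and its strand setting are not given in the sources used here. Reads of close gene copies, and of overlapping or antisense genes, may therefore be split or shared in ways that cannot be checked. The gene length deposited beside the counts is in bases and was not used to scale them.

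From the counts, genes were kept by edgeR's filterByExpr on the 3 groups, which left 15492 of 58735. Libraries were scaled by TMM and fitted together with edgeR 4.0.16 in R 4.3.3, with group as the only term and robust quasi-likelihood dispersions, and the 3 pairwise contrasts were tested two-sided with Benjamini-Hochberg adjustment over all tested genes. A gene was called at an adjusted p under 0.05, and counts with an added minimum of 2-fold are given beside. Log2 fold changes come with a standard error derived from the same test, the absolute log2 fold change divided by the square root of the F statistic. CPM values come with the SD over 3 libraries. Total counts per library ran from 15789722 to 24811150, so that 3 counts stand for 0.121 to 0.190 CPM. Intervals and floors cover counting error only.

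Before the data were examined, 28 lists of pathways, cell types and library quality were fixed. Lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the 27 such lists. With an estimated correlation camera called 0 lists in each comparison, with 3, 3 and 3 at an unadjusted p under 0.05 in YAP1 against MX, YAP1-S127A against MX and YAP1-S127A against YAP1, where fry called 4, 7 and 3. Median, mean and test differed in sign only for lists that were not called. These were TGF-beta targets and MYC in YAP1 against MX, MHC class I, epithelial junction and immediate early genes in YAP1-S127A against MX, and Hippo components, immediate early and leukocyte genes between the constructs. The symbols of 2 list members were matched by older names, CYR61 and CTGF.

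Genes named in the text were chosen by a rule fixed before the data were examined. It took YAP1, the 8 largest rises and 8 largest falls per comparison against MX (6 and 6 between the constructs) among called protein-coding genes with a mean log2 CPM of at least 3 and groups that did not overlap, up to 3 members of each called list with the smallest p, and the YAP targets ANKRD1, AMOTL2, CYR61 and CTGF. The level minimum did not hold for list members and the YAP targets, some of which had few counts. Not all genes that the rule took are named in the text, and genes named outside the rule are marked as such.

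Fold changes that share MX libraries were set beside 50 simulations of unchanged groups against the same libraries. Alternatives were other scalings (RLE, total counts), no or a stricter filter, protein-coding genes only, DESeq2 1.42.0, limma-voom, only the groups compared, tests against a minimum fold with edgeR's glmTreat, the replicate number as a block, each library left out in turn, and other list tests. Those chosen after seeing the data were leaving out mitochondrial genes, the mitochondrial share as covariate, YAP1-S127A reduced to replicate 2, and removal of chromosome-wide shifts. Base composition could not be checked per gene, since no human reference was at hand.

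The steps were tested on simulated counts of 15492 genes with 200 changed genes. At true folds of 1.5, 2 and 4 the test recovered 40.3%, 80.6% and 93.9% of changed genes for YAP1 against MX with 19 false calls, 41.8%, 76.1% and 95.5% for YAP1-S127A against MX with 11, and 29.9%, 76.1% and 89.4% for YAP1-S127A against YAP1 with 3. Correlation between libraries over genes was 0.983 to 0.990 within groups and 0.959 to 0.985 between groups. MX replicate 1 differed from MX replicates 2 and 3 in ways that this correlation does not show. It had 25491 genes detected, against 22115 and 22738. Its chromosome 19 genes had a median deviation from the MX mean of -0.242, against 0.147 and 0.090. Among fits without 1 library, those without MX replicate 1 gave the most changed genes in each comparison, 1423, 3079 and 465.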

Results

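RNA was sequenced from Caki cells, an established line of human clear cell renal carcinoma, carrying 1 of 3 retroviral constructs. MX was the empty vector, the YAP1 group carried wild-type YAP1, and the YAP1-S127A group carried YAP1 with alanine in place of the serine that the Hippo kinases LATS1 and LATS2 phosphorylate. YAP1 is a transcriptional coactivator that binds TEAD factors, and phosphorylation at that serine keeps it in the cytoplasm. Each group held 3 libraries, 9 in all, with 15789722 to 24811150 counts per library. The labels do not say whether the libraries of a group came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. The labels name the mouse as organism, but the count table lists 58735 human Ensembl genes, and the values are read here as human. Positions are those of the table, and the human build behind them is not given in the sources used here. On the first principal component, with 52.8% of the variance of the 2000 most variable genes, MX libraries lay from -34.9 to -33.5, YAP1 libraries from 2.37 to 6.35 and YAP1-S127A libraries from 27.0 to 31.6.

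Transcripts of the mitochondrial genome took 1.896 to 6.60% of the counts in the MX libraries, 3.50 to 11.4% in the YAP1 libraries and 7.40 to 29.6% in the YAP1-S127A libraries. The widest 95% Wilson interval of a library's share spanned 0.0443 percentage points, which covers counting error only. Means were 4.80% ± 2.54 (SD, n = 3) in MX, 7.84% ± 4.02 (SD, n = 3) with YAP1 and 19.4% ± 11.2 (SD, n = 3) with YAP1-S127A. In two-sided exact permutation tests p was 0.4 for YAP1 against MX, 0.1 for YAP1-S127A against MX and 0.3 for YAP1-S127A against YAP1, where 0.1 is the smallest p that 3 against 3 libraries allow.

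**Figure D1:**
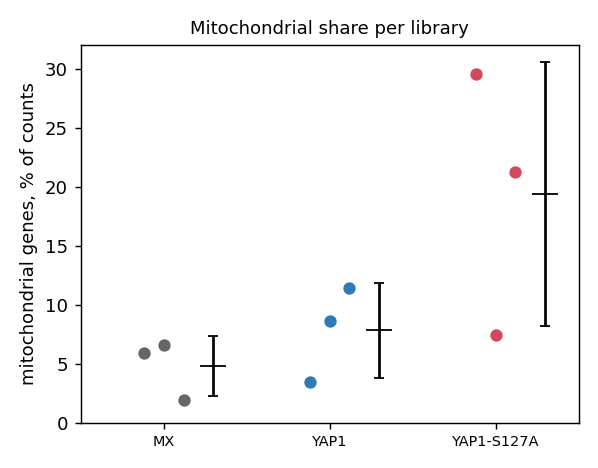
Percent of counts from the mitochondrial genome (y axis) in each of the 9 libraries by group, with points for libraries and bars for mean and SD. YAP1-S127A libraries span 7.40 to 29.6%, and MX libraries 1.896 to 6.60%.

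The YAP1 transcript was measured first, since it is the introduced gene. YAP1 (ENSG00000137693) lies on chromosome 11 from 102110461 to 102233423 on the plus strand. Its level was 99.9 ± 8.64 CPM (counts scaled to library size, SD, n = 3) in MX, 1220 ± 268 CPM with YAP1 and 688 ± 55.0 CPM with YAP1-S127A. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 fold change against MX was 3.61 (SE 0.16, adjusted p = 6.93e-11) with YAP1 and 2.78 (SE 0.16, adjusted p = 4.63e-10) with YAP1-S127A. The YAP1-S127A libraries held less of the transcript than the YAP1 libraries, by a log2 fold change of -0.83 (SE 0.15, adjusted p = 0.00383). Counts of the endogenous gene and of the construct were not separated in the table.

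**Figure D2:**
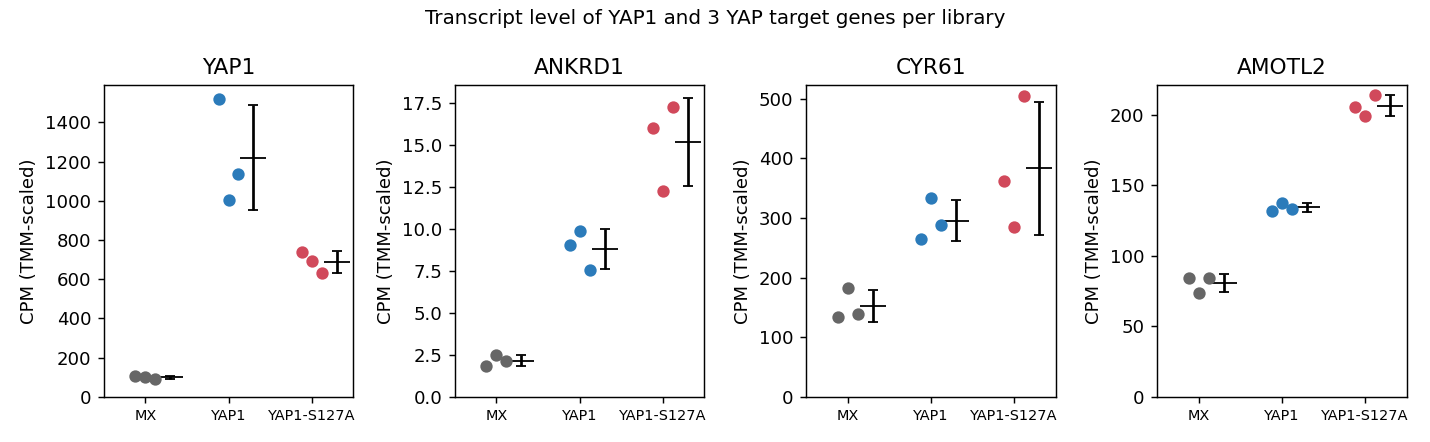
Level in CPM (y axis, from 0) of YAP1, ANKRD1, CYR61 and AMOTL2 in each library by group, with points for libraries and bars for mean and SD. YAP1 is highest with the wild-type construct, at 1220 CPM, while the means of the 3 target genes are highest with YAP1-S127A.

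The comparison of YAP1 with MX asks which transcripts differ when wild-type YAP1 is added. Among textbook YAP targets, ANKRD1, a nuclear ankyrin-repeat protein, rose by 2.05 on the log2 scale (SE 0.20, adjusted p = 1.91e-06). CYR61, a secreted matrix-associated protein, rose by 0.96 (SE 0.18, adjusted p = 0.00199), and AMOTL2, an angiomotin that binds YAP1, by 0.73 (SE 0.11, adjusted p = 0.000203). CTGF, another secreted target, had a log2 fold change of -0.07 (adjusted p = 0.845). Apart from the introduced YAP1, the largest rises among the abundant genes that the naming rule allowed were those of MSLN, the surface glycoprotein mesothelin, from 3.30 to 28.8 CPM (log2 fold change 3.17), and of CDH13, the cadherin without a cytoplasmic domain (3.06). SERINC2, a membrane protein, rose by 2.52 (adjusted p = 0.0352). KCNIP3, a calcium-binding protein, rose by 2.33, NPNT, a matrix ligand of integrins, by 2.33, MAL, a membrane protein of apical transport, by 2.14, and AOX1, an aldehyde oxidase, by 2.13. The largest falls among the abundant genes that the naming rule allowed were those of CLSTN2, a calsyntenin (-2.64), GDA, guanine deaminase (-2.09), and SERPING1, the inhibitor of complement C1 (-1.93). P3H3, of the prolyl 3-hydroxylase family (-1.87), SERPINF2, the plasmin inhibitor (-1.64), RGS5, a regulator of G-protein signalling (-1.60), ID1, an inhibitor of basic helix-loop-helix factors (-1.57), and PLA1A, a phospholipase (-1.53), fell as well. In all, 1055 of 15492 genes passed an adjusted p of 0.05, 500 higher and 555 lower with YAP1, and 398 of them differed at least 2-fold (159 higher and 239 lower). Scaled to total counts, 311 were higher and 679 lower, and at 2-fold 140 and 315. The 3 libraries of each group did not overlap for 24.1% of tested genes, where chance gives 10%.

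By gene list, 8 of 21 tested members of the YAP/TAZ target signature rose with YAP1 and the other 13 did not pass, and 13 rose when adjusted over the list alone. Limma's camera called this list (adjusted p = 5.01e-08, and adjusted p = 0.252 with an estimated correlation), and AXL, a receptor tyrosine kinase, rose by 0.81. Of 27 genes of the actin cytoskeleton and focal adhesion 4 rose, 13 adjusted over the list alone (adjusted p = 8.41e-06, and adjusted p = 0.331 with an estimated correlation). CAVIN1, a caveolar coat protein, rose by 0.75. Of 26 Hippo pathway components 3 rose, 3 adjusted over the list alone (adjusted p = 0.0276, and adjusted p = 0.489 with an estimated correlation). VGLL3, a TEAD cofactor, rose by 2.15, from only 0.575 to 2.63 CPM, and FRMD6, an upstream scaffold, by 0.93. Cholesterol synthesis had 4 of 22 members higher, 6 adjusted over the list alone (adjusted p = 0.00150, and adjusted p = 0.489 with an estimated correlation). MVD, a mevalonate pathway enzyme, rose by 0.60. Among 25 NF-kB and inflammatory cytokine genes 3 rose, 3 adjusted over the list alone (adjusted p = 0.00270, and adjusted p = 0.489 with an estimated correlation). The 3 were the cytokines CSF2 (1.78, from only 0.486 to 1.68 CPM) and IL6 (1.55) and the chemokine CXCL1 (1.02). Of 29 collagens and matrix proteins 5 rose and 2 fell, 10 and 4 adjusted over the list alone (adjusted p = 0.0154, and adjusted p = 0.699 with an estimated correlation). COL12A1, a fibril-associated collagen, rose by 2.01 and LAMB3, a laminin chain, by 1.21, while LAMA4, another laminin chain, changed by -0.96. COL12A1, LAMA4, CTGF and the kidney gene SLC17A1 lie on chromosome 6, whose genes had a median log2 fold change of 0.22 in this comparison. With chromosome-wide shifts removed CTGF had -0.28 (adjusted p = 0.292).

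Genes of the kidney tubule and PAX8 lineage were lower with YAP1 in 6 of 12 tested members and higher in 1, and 7 and 1 adjusted over the list alone (adjusted p = 0.0129, and adjusted p = 0.268 with an estimated correlation). CDH6, a cadherin of the proximal tubule, changed by -1.08 and SLC17A1, a phosphate and urate transporter, by -1.12, while MME, the peptidase neprilysin, rose by 1.94. Of 19 NRF2 targets 5 fell, and 6 fell and 1 rose adjusted over the list alone (adjusted p = 0.0276, and adjusted p = 0.494 with an estimated correlation). NQO1, a quinone reductase, changed by -0.57 and AKR1C3, an aldo-keto reductase, by -1.16, the latter uncertain because AKR1C genes are close copies that can share reads. Of 35 interferon-stimulated genes 4 fell, 4 adjusted over the list alone (adjusted p = 0.0498, and adjusted p = 0.489 with an estimated correlation). IFITM1, which restricts viral entry, changed by -1.96, from only 3.21 to 0.818 CPM, and IFI44L by -0.99. The G1/S and DNA replication list was called upward (adjusted p = 0.0276, and adjusted p = 0.494 with an estimated correlation). Of its 28 members 1 passed the test, GINS1 of the replicative helicase at 0.45 (adjusted p = 0.0375), and 0 adjusted over the list alone. At an unadjusted p under 0.05 edgeR gave 5 of these 28, and DESeq2 and limma-voom each called 2. The mitochondrially encoded list was also called upward (adjusted p = 0.0498, and adjusted p = 0.795 with an estimated correlation). Its 13 members gave 0 past edgeR's test, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom.

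Without YAP1 replicate 3 the count of changed genes was 601 and without YAP1 replicate 2 it was 639, and the calls of CXCL1 (adjusted p = 0.116 without MX replicate 1), GINS1 (0.0758 to 0.149 without any of MX replicates 1 and 3 and YAP1 replicates 1, 2 and 3), P3H3 (0.0532 without YAP1 replicate 3) and SERINC2 (0.0587 to 0.126 without any of MX replicates 1, 2 and 3, YAP1 replicate 2 and YAP1-S127A replicates 2 and 3) were lost. Among list members that the naming rule took, calls were likewise lost for CDC42EP3 (0.0799 to 0.104 without MX replicate 2 or YAP1 replicate 1 or 2), WWC1 (0.0818 to 0.199 without MX replicate 2 or 3 or YAP1 replicate 2 or 3), BST2 (0.0515 to 0.0752 without MX replicate 2 or 3 or YAP1 replicate 3) and LSS (0.0520 without YAP1 replicate 3). List calls were lost without MX replicate 3 for NRF2 targets (adjusted p = 0.167), collagens (0.0599, and 0.0674 without YAP1 replicate 2), interferon genes (0.165, and 0.0526 to 0.0926 without MX replicate 1, YAP1 replicate 1 or 2 or YAP1-S127A replicate 1 or 3) and mitochondrially encoded genes (0.627, and 0.0670 to 0.351 without YAP1 replicate 2 or 3 or YAP1-S127A replicate 3), and without MX replicate 2 for Hippo components (0.130) and the G1/S list (0.108, and 0.0701 and 0.0779 without MX replicate 1 or YAP1 replicate 3).

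The comparison of YAP1-S127A with MX asks the same of the constitutively active form. MSLN rose from 3.30 ± 1.24 to 128 ± 31.6 CPM (SD, n = 3), a log2 fold change of 5.33 (SE 0.27, adjusted p = 3.06e-08). FGFBP1, a carrier of fibroblast growth factors, rose by 3.67, CDH13 by 3.62 and EFEMP1, a fibulin of the matrix, by 3.31. MAL rose by 3.26, AOX1 by 2.76 and TAGLN, the actin-binding transgelin, by 2.76. CLDN2, a claudin of leaky tight junctions such as those of the proximal tubule, fell from 868 ± 51.3 to 127 ± 17.7 CPM (SD, n = 3), a log2 fold change of -2.77 (SE 0.14, adjusted p = 2.12e-10). Other large falls were those of SERPING1 (-3.43), SERPINF2 (-2.82) and NYNRIN (-2.60). Lower levels were also found for ADGRG2, an adhesion G-protein-coupled receptor (-2.36), NES, the intermediate filament nestin (-2.34), and DLGAP1, a scaffold protein (-2.29). FOXQ1, a forkhead factor, fell by 2.42 with all libraries (adjusted p = 0.0179), and its adjusted p was 0.0791 without YAP1-S127A replicate 3. In edgeR's test 2845 of 15492 genes passed an adjusted p of 0.05, 1476 higher and 1369 lower. Of these, 964 differed at least 2-fold, 455 higher and 509 lower. Scaled to total counts, 611 were higher and 3836 lower, and at 2-fold 321 and 965. Total counts include mitochondrial transcripts, on average 19.4% with YAP1-S127A and 4.80% in MX, which lowers the other genes under this scaling. How much of the imbalance this makes up was not tested. Groups did not overlap for 32.6% of genes, where chance gives 10%.

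Among the YAP targets ANKRD1 rose by 2.84 (SE 0.20, adjusted p = 7.70e-09), AMOTL2 by 1.35 (SE 0.11, adjusted p = 4.27e-08) and CYR61 by 1.34 (SE 0.18, adjusted p = 3.48e-05). CTGF had a log2 fold change of 0.35 (adjusted p = 0.107). The YAP/TAZ target signature had 12 of 21 members higher and 9 that did not pass, 18 higher adjusted over the list alone (camera adjusted p = 6.27e-10, and adjusted p = 0.0900 with an estimated correlation). Of 12 kidney tubule genes 8 fell and 1 rose, 9 and 1 adjusted over the list alone (adjusted p = 0.000493, and adjusted p = 0.0900 with an estimated correlation). CDH6 changed by -2.21, SLC4A4, a bicarbonate transporter, by -1.52 and MME by 2.40. Of 10 fibroblast and stroma genes 6 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.000493, and adjusted p = 0.207 with an estimated correlation). LUM, the proteoglycan lumican, rose by 3.53, MFAP5, a microfibril protein, by 2.01 and COL1A1 by 1.60. LUM and MFAP5 were low, from 0.871 to 9.53 and from 0.823 to 3.41 CPM, while COL1A1 went from 929 to 2826 CPM. Of 18 mesenchymal genes 4 rose, 4 adjusted over the list alone (adjusted p = 0.0300, and adjusted p = 0.576 with an estimated correlation). The calcium-binding protein S100A4 rose by 1.77, the gelatinase MMP2 by 1.52 and SPARC, a collagen-binding matrix protein, by 0.97. Collagens and matrix proteins had 13 of 29 members higher and 6 lower, 13 and 6 adjusted over the list alone (adjusted p = 0.0428, and adjusted p = 0.868 with an estimated correlation). COL12A1 changed by 2.60, LAMB3 by 1.62 and LAMA4 by -1.79. The median log2 fold change of chromosome 6 genes, among them COL12A1, LAMA4, FOXQ1 and CTGF, was 0.18 here, and with such shifts removed CTGF had 0.16 (adjusted p = 0.476).

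Of 27 actin and focal adhesion genes 9 rose with YAP1-S127A, 10 adjusted over the list alone (adjusted p = 0.000493, and adjusted p = 0.524 with an estimated correlation). Among them were CAVIN1 at 1.03, CAV1, the caveolar protein, at 0.85 and LIMA1, an actin bundler, at 0.84. Of 25 NF-kB genes 9 rose and 1 fell, 10 and 2 adjusted over the list alone (adjusted p = 0.00340, and adjusted p = 0.624 with an estimated correlation). Here were CSF2 at 3.65 (from 0.486 to 6.18 CPM), IL6 at 2.26 and CXCL1 at 1.16. Cholesterol synthesis had 4 of 22 members higher, 7 adjusted over the list alone (adjusted p = 0.0300, and adjusted p = 0.813 with an estimated correlation), with MVD at 0.86. NRF2 targets had 5 of 19 members lower and 2 higher, 6 and 2 adjusted over the list alone (adjusted p = 0.0300, and adjusted p = 0.678 with an estimated correlation), with NQO1 at -0.70 and AKR1C3 at -1.57. The mitochondrially encoded list was called upward (adjusted p = 5.46e-05, and adjusted p = 0.678 with an estimated correlation). Of its 13 members 0 passed edgeR's test, 13 adjusted over the list alone, 13 at an unadjusted p under 0.05, 13 by DESeq2 and 0 by limma-voom. MT-ND1 had a log2 fold change of 2.88 (edgeR adjusted p = 0.0933, DESeq2 adjusted p = 0.00277).

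The count was 1847 without YAP1-S127A replicate 3, 1278 with YAP1-S127A replicate 2 alone, where the mitochondrially encoded list had an adjusted p of 0.0632, and 1286 with the mitochondrial share as covariate, where 4 lists were called, those of YAP/TAZ targets, actin, fibroblast and kidney tubule genes. Scaling to total counts, which moved the median of all genes by -0.28, gave 4447 genes, and calls were lost for CXCL1 (adjusted p = 0.0533 without MX replicate 1) and without single libraries for cholesterol synthesis (adjusted p = 0.201 without YAP1-S127A replicate 3, 0.121 without MX replicate 1), collagens (0.167 without YAP1-S127A replicate 2, 0.0858 without YAP1-S127A replicate 3, 0.0552 without MX replicate 3), mesenchymal genes (0.0671 without YAP1-S127A replicate 2, 0.0552 without MX replicate 3) and NRF2 targets (0.125 without MX replicate 3, 0.0864 without YAP1-S127A replicate 3).

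**Figure D3:**
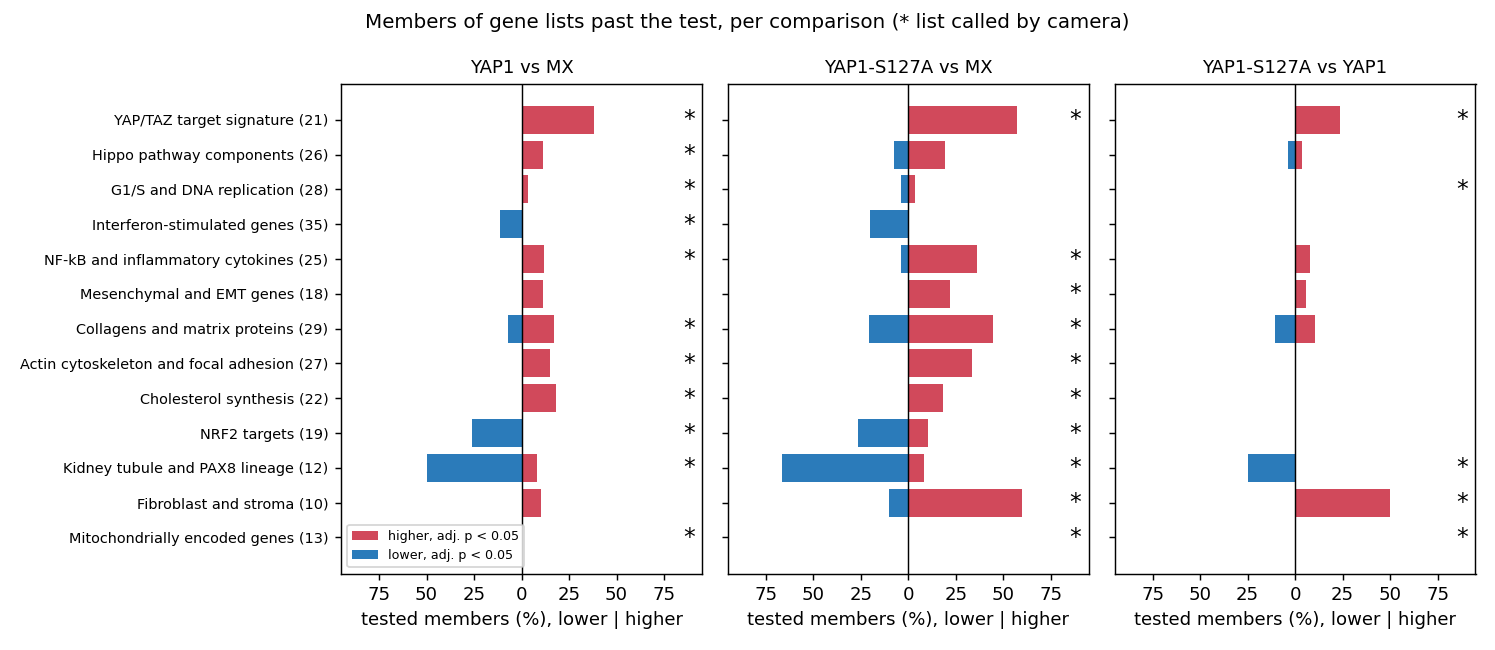
Percent of tested members (x axis) higher or lower at an edgeR adjusted p under 0.05 for 13 gene lists (y axis) in each comparison, with an asterisk for lists called by camera. Of the YAP/TAZ target signature 8 of 21 members are higher with YAP1 and 12 of 21 with YAP1-S127A.

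The direct comparison of YAP1-S127A with YAP1 asks where the constructs differ. EFEMP1 was higher with YAP1-S127A by 2.69 on the log2 scale (SE 0.39, adjusted p = 0.00980), MSLN by 2.16 (SE 0.23, adjusted p = 0.000386), GFRA1, a receptor for glial-derived neurotrophic factor, by 1.76, FGFBP1 by 1.69, TAGLN by 1.55 and LRRC32, a carrier of latent TGF-beta, by 1.42. CLDN2 was lower, at 127 against 376 ± 46.0 CPM (log2 fold change -1.57, SE 0.13, adjusted p = 7.05e-06), as were ADGRG2 (-1.60), SERPING1 (-1.50), NYNRIN (-1.40), CDH1, the epithelial cadherin (-1.28), and SYT13, a synaptotagmin (-1.18). Of the textbook targets AMOTL2 was higher by 0.62 (adjusted p = 0.00322) and ANKRD1 by 0.79 (adjusted p = 0.0194), while CTGF (0.42, adjusted p = 0.188) and CYR61 (0.38, adjusted p = 0.393) did not pass. In edgeR's test 305 of 15492 genes passed, 175 higher and 130 lower, and 124 differed at least 2-fold, 85 higher and 39 lower. Scaled to total counts the larger share was lower, with 113 higher and 503 lower, and at 2-fold 72 and 131. The mitochondrial share in those totals was on average 19.4% with YAP1-S127A and 7.84% with YAP1, which lowers the other genes under this scaling. Groups did not overlap for 19.6% of genes, where chance gives 10%.

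The YAP/TAZ target signature had 5 of 21 members higher with YAP1-S127A than with YAP1, 9 adjusted over the list alone (camera adjusted p = 3.11e-06, and adjusted p = 0.159 with an estimated correlation). TGFB2, a transforming growth factor, stood at 1.36 and CRIM1, a membrane protein that binds BMPs, at 0.80. Of 10 fibroblast and stroma genes 5 were higher, 6 adjusted over the list alone (adjusted p = 3.11e-06, and adjusted p = 0.123 with an estimated correlation). LUM stood at 1.92, MFAP5 at 1.54 and PDGFRB, a receptor of platelet-derived growth factor, at 0.85. Kidney tubule genes were lower in 3 of 12 members, 5 adjusted over the list alone (adjusted p = 0.00174, and adjusted p = 0.123 with an estimated correlation). CDH6 stood at -1.13, SLC4A4 at -0.89 and DPP4, a brush border peptidase, at -0.59. The G1/S list was called downward (adjusted p = 0.0154, and adjusted p = 0.850 with an estimated correlation). Its 28 members gave 0 past edgeR's test, 0 adjusted over the list alone, 4 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. UHRF1, a factor of maintenance DNA methylation, stood at -0.36 (adjusted p = 0.126). The mitochondrially encoded list was called upward (adjusted p = 1.67e-05, and adjusted p = 0.850 with an estimated correlation). Here 0 of 13 members were past edgeR's test, 0 adjusted over the list alone, 0 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom.

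Without single libraries the count was 465 (MX replicate 1), 189, 166 and 144 (YAP1 replicates 1, 2 and 3), 188 and 126 (YAP1-S127A replicates 2 and 3), it was 151 with YAP1-S127A replicate 2 alone, where the mitochondrially encoded list had an adjusted p of 0.591, and scaling to total counts gave 616 and ended the calls of AMOTL2 (adjusted p = 0.124) and ANKRD1 (0.0822). Calls were also lost for ANKRD1 (adjusted p = 0.168 without YAP1-S127A replicate 3, 0.143 and 0.0773 without YAP1 replicates 3 and 1, 0.0647 without YAP1-S127A replicate 1), EFEMP1 (0.0535 without YAP1 replicate 2), GFRA1 (0.0683 without MX replicate 1), MFAP5 (0.0652 without YAP1 replicate 3), CRIM1 (0.0604 without YAP1-S127A replicate 3), SLC4A4 (0.0532 without YAP1 replicate 3), DPP4 (0.0852 to 0.143 without YAP1 replicate 2 or 3 or YAP1-S127A replicate 2 or 3) and the G1/S list (0.132 without YAP1-S127A replicate 3, 0.0718 without YAP1 replicate 3).

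Most genes called with YAP1 against MX were also called with YAP1-S127A. Of 1055 genes called with YAP1, 922 were also called with YAP1-S127A in the same direction, 440 higher and 482 lower, and 1052 had the same sign. Independent lists of these sizes would share 96.7 genes, and 50 simulations of unchanged groups against the same MX libraries gave a mean of 0.06. The simulated lists held 0.78 and 0.6 genes on average, so the last value says little about lists of the real sizes. The fold changes correlated across genes at r = 0.81, against 0.48 simulated, with a covariance of 0.264 against 0.0322 simulated, an excess of 0.231. Genes are not independent replicates, and with 3 MX libraries that could not be divided, part of the excess over independent lists may come from the shared controls. Of the 922 genes, 735 (79.7%) had the larger change with YAP1-S127A, and the slope of its fold changes on those of YAP1 was 1.38 after the simulated noise was removed (95% bootstrap interval over genes 1.33 to 1.42). The variance of the YAP1 fold changes was 0.234, against 0.0661 simulated. Without this removal the slope is the covariance of 0.264 over the variance of 0.234, which is smaller. The size of 1.38 therefore depends on the simulated noise, which was drawn independently for each gene. The interval holds the simulated noise fixed and covers no spread between libraries. Fits without 1 library gave slopes of 1.25 to 1.37. Without YAP1 replicates 2 and 3 in turn the shared count was 570 and 553.

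**Figure D4:**
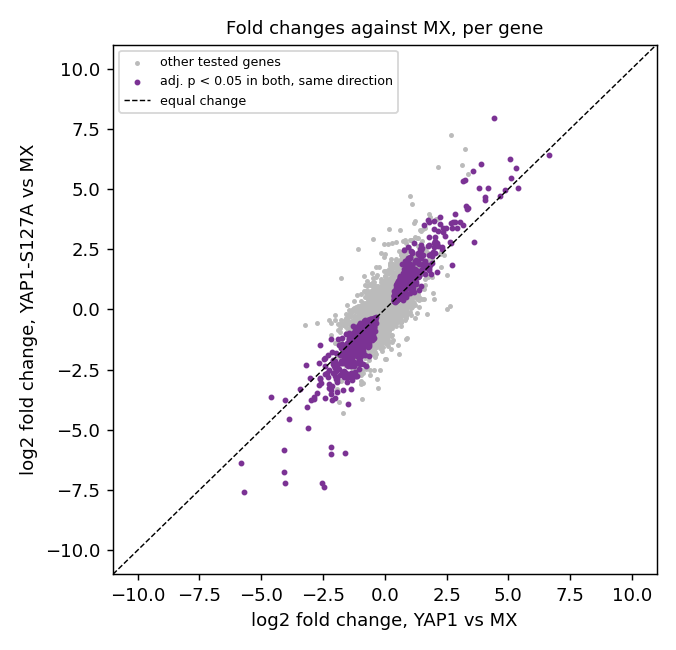
Log2 fold change with YAP1-S127A against MX (y axis) by log2 fold change with YAP1 against MX (x axis), 1 point per tested gene, with purple for the 922 genes called in both in the same direction and a dashed line for equal change. Most purple points lie on the side of larger change with YAP1-S127A.

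The other lists were not called by camera, and their counts by edgeR follow in the order YAP1 against MX, YAP1-S127A against MX and YAP1-S127A against YAP1. TGF-beta targets had 4, 5 and 3 of 18 members higher and 4, 3 and 1 lower. ERBB ligands and receptors had 2, 3 and 1 of 12 higher and 0, 2 and 1 lower, and immediate early genes 0, 4 and 3 of 21 higher and 0, 4 and 0 lower. Epithelial junction genes had 1, 1 and 0 of 16 higher and 2 lower in each comparison. The unfolded protein response list had 0, 4 and 2 of 22 higher and 1, 2 and 0 lower, MYC and ribosome biogenesis 2, 1 and 0 of 22 higher and 0, 1 and 0 lower, and p53 targets 1, 1 and 0 of 24 higher and 0, 1 and 0 lower. Hypoxia targets had 1, 4 and 0 of 24 lower, glycolysis 0, 2 and 0 of 17 lower, and MHC class I genes 0, 2 and 0 of 16 higher. G2/M genes had 0, 2 and 0 of 28 higher and 0, 1 and 0 lower, and cytosolic ribosomal proteins 0, 1 and 0 of 39 higher and 1, 3 and 0 lower. Among markers of other cell types, keratinocyte genes had 1, 3 and 0 of 7 higher and 0, 1 and 0 lower, leukocyte genes 0, 1 and 1 of 6 higher and 1, 2 and 0 lower, and endothelial genes 1, 1 and 0 of 3 higher, too few for the list test. Of these lists with 0 members past edgeR's test in a comparison, DESeq2 called 2 immediate early genes in YAP1 against MX and 1 hypoxia target between the constructs, where 6 and 4 had an unadjusted edgeR p under 0.05. For the others DESeq2 called 0, limma-voom called 0 for all, and 0 to 3 members had such a p.

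Lists called in only some comparisons had these counts in the others. With YAP1-S127A against MX, 5 of 26 Hippo components were higher and 2 lower, 7 of 35 interferon-stimulated genes were lower, and of the G1/S list 1 of 28 was higher and 1 lower. With YAP1 against MX, 1 of 10 fibroblast genes and 2 of 18 mesenchymal genes were higher. With YAP1-S127A against YAP1, 3 of 29 matrix genes were higher and 3 lower, 2 of 25 NF-kB genes and 1 of 18 mesenchymal genes were higher, and 1 of 26 Hippo components was higher and 1 lower. In that comparison 0 of 27 actin genes passed edgeR's test, with 5 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-voom, and 0 of 22 cholesterol genes, with 2, 0 and 0. Of 19 NRF2 targets and 35 interferon-stimulated genes 0 passed there, with 2 each at an unadjusted p under 0.05, 1 each by DESeq2 and 0 by limma-voom.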

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

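Of the tests below, the placing of single libraries by mitochondrial share and the fit with YAP1-S127A replicate 2 alone were chosen only after the result was seen. The effects of the constructs against the same MX libraries were compared by the direct test of YAP1-S127A against YAP1, and 6 results passed it, of which 5 are list calls. At least 5 lists were also called in 9 of the 10 splits of these 6 samples, the real one included, with up to 12 in another split. The YAP1 transcript was lower with YAP1-S127A (log2 fold change -0.83, edgeR adjusted p = 0.00383). By camera the YAP/TAZ target signature (adjusted p = 3.11e-06, and 0.159 with an estimated correlation) and fibroblast and stroma genes (adjusted p = 3.11e-06, and 0.123 with an estimated correlation) were higher. Kidney tubule genes (adjusted p = 0.00174, and 0.123 with an estimated correlation) and the G1/S list (adjusted p = 0.0154, and 0.850 with an estimated correlation) were lower. The mitochondrially encoded list was higher (adjusted p = 1.67e-05, and 0.850 with an estimated correlation), while the mitochondrial share had an exact permutation p of 0.3. Of the G1/S and mitochondrially encoded members, 0 passed by edgeR, DESeq2 or limma-voom, and 4 and 0 had an unadjusted edgeR p under 0.05.

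The mitochondrial share was 19.4% ± 11.2 (SD, n = 3) with YAP1-S127A and 4.80% ± 2.54 in MX. More transcription of the whole respiratory chain is argued against, since its 61 nuclear genes had a median log2 fold change of -0.12 against MX (SE 0.101 between libraries). Composition of single libraries, such as RNA quality, may contribute, because 2 of the 3 YAP1-S127A libraries lay above the highest of the other 6 and the remaining one, at 7.40%, lay within their range. Whether the construct itself raises mitochondrial transcripts stays open, since the tests between groups cannot tell it apart from differences in library quality.

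Fold changes were larger with YAP1-S127A than with YAP1, with a slope of 1.38 after the simulated noise was removed, although its YAP1 transcript was lower. The slope is smaller without that removal. Chance values of the shared controls are argued against, since they add the same amount to both fold changes and so pull the slope toward 1. The lowest slope of the 9 fits without 1 library was 1.25, without YAP1 replicate 1. For these fits and that with YAP1-S127A replicate 2 alone, noise was simulated in 5 draws for 15492 genes. They tested 15708 to 16657 genes, so their slopes are not on the same footing as 1.38. The libraries with the highest mitochondrial share also stay open as a cause, since the slope of 1.27 without them rests on YAP1-S127A replicate 2 alone. Higher activity of the changed protein may underlie the slope, as a hypothesis that was not tested, since no protein was measured.

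Each pair of groups allows 10 splits of its 6 samples, too few for a share under 0.05. For genes changed, the real counts were 1055, 2845 and 305 for YAP1 against MX, YAP1-S127A against MX and YAP1-S127A against YAP1, and the highest of the other splits gave 1 in each. For changes of at least 2-fold the real counts were 398, 964 and 124, and the highest other was again 1 in each. For lists called, the real counts were 11, 10 and 5 and the highest others 9, 14 and 12, and counts as large came from 1, 3 and 9 of the 10 splits, the real one included. The overlap of 922 genes was reached by 1 of 100 drawn splits of the 9 samples, the real one (highest other 814). The correlation of 0.81 was reached by 3 of 100, the real one included (highest other 0.859). Only 2 of the other draws kept MX whole, so these shares show that the MX libraries stood apart from the other 6. They do not exclude a chance difference between the cell populations, since libraries of a group may be technical repeats. Nor do they bear on how these 6 were divided. The highest others came from splits that kept MX whole, and where MX was split the highest values were 1 gene and 0.790.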

How the results depend on the processing

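Of the values for named genes under alternatives chosen before the data were examined, 2147 kept their direction and side of the threshold, 61 lost the call, 11 gained one and 1 reversed, and under alternatives chosen after seeing the data 491 kept both, 20 lost, 2 gained and 2 reversed. For called lists the earlier alternatives kept 361 and lost 81, and the later ones kept 79, lost 21 and reversed 1. RLE scaling, DESeq2 and limma-voom gave 1059, 1176 and 1063 genes for YAP1 against MX, 2840, 2953 and 2851 for YAP1-S127A against MX and 288, 443 and 274 for YAP1-S127A against YAP1, and removing chromosome-wide shifts 969, 2780 and 305. Unless stated, the cause was not tested.

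For YAP1 against MX, 540 genes passed against a fold of 1.2 and fits without 1 library gave 601 to 1423. The 2-fold count was 232 with the strict filter, which tests fewer genes, 84 against a fold of 2, which asks for more than the estimate, and 319 to 424 without 1 library. For YAP1-S127A against MX the count was 4447 with total counts, 1631 against a fold of 1.2, 1286 with the mitochondrial covariate, of which 1216 were among the calls of the full design, 1278 with YAP1-S127A replicate 2 alone, which has fewer samples, of which 1175 were, and 1847 to 3079 without 1 library. Its 2-fold count was 511 with the strict filter, 317 against a fold of 2 and 816 to 1000 without 1 library. For YAP1-S127A against YAP1 it was 616 with total counts, 520 without a filter, 478 with only the 2 groups, 151 with replicate 2 alone, 134 against a fold of 1.2 and 126 to 465 without 1 library. Its 2-fold count was 203 with total counts, 76 with the strict filter, 81 to 169 without 1 library, and 0 against a fold of 2 by edgeR's glmTreat, with 142 at an unadjusted p under 0.05.

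With the replicate number as a block 1428, 3426 and 472 genes passed. The labels do not pair the libraries. Deviations of the 9 same-numbered pairs correlated at -0.18 to 0.20, 1 over 0.1. In both other groups at once, 0 of 9 libraries correlated best with their own number. MX replicate 1 and YAP1-S127A replicate 1 were each other's best match (0.20), while MX replicate 3 and YAP1-S127A replicate 2, of unlike number, stood at 0.21. A shared batch is not excluded by these values.

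Camera with an estimated correlation called 0, 0 and 0 lists. Fry called 4 for YAP1 against MX and 3 between the constructs, the mitochondrial covariate left 4 for YAP1-S127A against MX and 3 between the constructs, replicate 2 alone gave 8 there, and fits without 1 library gave 8 to 14, 7 to 11 and 4 to 8.

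The YAP1 transcript between the constructs stayed at -0.83 with replicate 2 alone without passing, and ran from -0.96 to -0.64 without 1 library, from 3.42 to 3.74 for YAP1 against MX and from 2.71 to 2.85 for YAP1-S127A against MX. The correlation of fold changes was 0.503 without a filter, where genes of few counts enter, 0.849 with the strict filter, 0.834 for protein-coding genes, 0.623 with replicate 2 alone and 0.760 to 0.822 without 1 library, and the overlap ran from 553 to 1170. Reversed values, none past the threshold, were CTGF for YAP1 against MX, at 0.063 without YAP1 replicate 1 and from -0.19 to 0.063 over fits without 1 library, MT-ND3 at -0.14 and CYR61 at -0.063 between the constructs with replicate 2 alone, and the mitochondrially encoded list for YAP1 against MX (adjusted p = 0.813) with the covariate, which is built from these genes. At 3 libraries per group, changes near 1.5-fold were mostly missed in simulated counts.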

Other observations

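The genes below were chosen after their values were seen, and of the tests of chromosome 6 those with the mitochondrial covariate, with chromosome 19 and on windows were chosen only after the result was seen. Some genes were near silent in MX, under 0.2 CPM, and above 2 CPM with a construct, or the reverse. BRINP2 and its neighbour ASTN1 on chromosome 1, both linked to neural development, had 4 and 5 counts over the 3 MX libraries, 364 and 177 with YAP1 and 258 and 220 with YAP1-S127A. PI3, the elastase inhibitor elafin, had 13, 157 and 303. USH1C, CDC20B and RTL1 went the other way in both comparisons. With YAP1-S127A 8 genes appeared in this way, among them PCSK5, COL11A1, FGFR2, IL7R and CHRDL1, and 9 were lost, among them TSHR, the thyrotropin receptor, with 313 counts in MX and 1 with YAP1-S127A, TRABD2B and FXYD2, a regulator of the sodium pump in the kidney.

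Ligands of ERBB receptors went different ways in edgeR's test: HBEGF rose by 0.63 with YAP1 and 1.18 with YAP1-S127A, EREG rose by 0.60 with YAP1 and had a log2 fold change of 0.00 (adjusted p = 0.996) with YAP1-S127A, and AREG changed by -0.92 with YAP1-S127A and by -0.21 (adjusted p = 0.531) with YAP1. Among TGF-beta targets ID2, an inhibitor of basic helix-loop-helix factors, changed by -1.15 and -1.85. The epithelial genes CDH1 (-0.65 and -1.93) and EPCAM (-1.12 and -1.16) fell with both constructs, and DSP, the desmosomal plaque protein, rose with YAP1 by 1.07 (0.48 with YAP1-S127A, adjusted p = 0.0712). COL1A2 rose by 6.68 with YAP1-S127A and had 3.25 with YAP1 (adjusted p = 0.0511).

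Genes of chromosome 6 were higher as a whole in both YAP1 groups than in MX: the median log2 fold change of its 482 genes with a mean log2 CPM of at least 3 was 0.22 (bootstrap SE over genes 0.012) with YAP1 and 0.18 (SE 0.015) with YAP1-S127A, while the other 22 chromosomes lay from -0.12 to 0.10 and from -0.07 to 0.11. Some of these were shifted too. With YAP1, chromosomes 12 and 10 had -0.12 (SE 0.011) and -0.10 (SE 0.0089), and chromosome 9 had 0.096 (SE 0.011). On chromosome 3 the 10 Mb windows covering MME and AMOTL2 had medians of 0.14 and 0.12 with YAP1. With YAP1-S127A they had 0.38 and 0.19. All windows of this chromosome from 80 to 200 Mb had positive medians with YAP1-S127A, from 0.038 to 0.38. Those under 80 Mb had -0.14 to 0.072. With YAP1 the medians were -0.015 to 0.20 from 80 Mb on and -0.093 to 0.14 under it. These windows held 5 to 77 genes. Removal of chromosome-wide shifts centred whole chromosomes, so it did not take out such a step, in whose higher part VGLL3, MME and AMOTL2 lie. Library composition as far as the mitochondrial share measures it is argued against, since with that share as covariate the smaller of the 2 medians was 0.19 (SE 0.018). Other differences in composition were not tested this way and stay open. Base composition is argued against as far as chromosome 19, rich in G and C, tracks it. Among the MX libraries the chromosome 19 median ran from -0.242 to 0.147, while the chromosome 6 median stayed from -0.0028 to 0.0124. The chromosome 6 median was 0.205 to 0.239 in the YAP1 libraries and 0.182 to 0.212 in the YAP1-S127A libraries. Between groups chromosome 19 differed by only -0.016 and -0.040 (SE 0.103). With its median per library as covariate, the smaller chromosome 6 difference was 0.19 (SE 0.0126 between libraries). That covariate could hardly move the difference, since it varied little between groups. Base composition that chromosome 19 does not track stays open. A difference in copy number between the cell populations may also underlie the shift and stays open, as no DNA was measured. Of the chromosome's 15 windows of 10 Mb 93.3% lay above 0.05 in both comparisons, against 23.1% of 260 elsewhere, which follows in part from picking the chromosome with the highest median. Of all 796 tested genes on this chromosome, whatever their level, 76 were called higher and 18 lower with YAP1, and 141 and 45 with YAP1-S127A.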
